A study of Mus musculus with 12 samples.

How the data were processed

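The samples were 12 RNA-seq libraries of female mouse embryonic stem (ES) cells, described by the labels as C57BL6/CAST hybrids, so that the 2 parental chromosomes differ at many single-base positions. Each label names a genotype (wild type or knockout of the sirtuin gene Sirt7), a day (0 or 7) and a replicate number. Per the labels' protocols, day 0 cells grew with leukaemia inhibitory factor (LIF, which holds ES cells in the undifferentiated state) and day 7 cells were taken 7 days after its withdrawal; RNA was extracted with TRIzol, selected for polyA and made into libraries with NEBNext kits. A further treatment label (LIF or none) ran by replicate and genotype rather than by day and was not used for grouping.

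Per the submitters' processing notes, the tools were FastQC 0.11.3, Trimmomatic 0.36, HISAT2 2.1.0, SAMtools 0.1.19, StringTie 1.3.3 and DESeq2 1.32.0, with the builds mm10 and GRCm38. Their settings, the annotation release and any use of strand in counting are not given in the sources used here. The authors deposited expected counts (reads per gene and per transcript as StringTie estimates them, not normalized) for all reads, and a second set of expected counts per gene divided into genome 1, genome 2 and unassigned reads. The column names do not say which parental strain is genome 1, so the names genome 1 and genome 2 are kept. The values were whole numbers and were tested as deposited. Without strand, reads of Xist and of its antisense partner Tsix cannot be told apart where they overlap, and members of gene families with close copies or pseudogenes (ribosomal proteins, Zscan4, Xlr3, Rhox) are uncertain.

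Gene identifiers were matched to the GENCODE annotation of GRCm38 given for this work: 55227 of 55487 identifiers matched, or 99.53%, and 96.72% carried the same symbol. Library totals ran from 25190483 to 69079368 counts, which sets the precision: a gene with a group total of 3 counts or fewer was taken to be at the floor, and a fold against a group with no count was computed against 3 counts over that group and written as a lower bound. Intervals are 95% intervals. Those of medians over genes are bootstraps over genes, which measure the spread between genes and not between libraries. Other intervals and floors cover counting error only, since reads of a PCR-amplified library are not independent molecules. Replicate libraries of a group all differed by more than sampling noise, with a chi-square per degree of freedom of 24.8 to 61.7 over genes, so that none was counted as a repeat of another.

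Expression was tested in R 4.3.3 with edgeR 4.0.16 (filterByExpr by group, TMM normalization, quasi-likelihood fit and test, 1 coefficient per group, all 12 libraries in 1 fit), which left 19235 genes. Each fold change is a log2 value with its standard error (SE), and adjusted p is Benjamini-Hochberg over all genes tested, with a threshold of 0.05. CPM values are counts scaled to the TMM library sizes and are given as mean ± SD of n = 3. The comparisons were knockout against wild type at day 0 and at day 7, day 7 against day 0 in each genotype, and the interaction (the change over 7 days in knockout minus that in wild type). X-linked genes were tested against autosomal genes, and each gene list against all other genes, with camera in limma 3.58.1 at its preset correlation of 0.01 on log2 CPM with a prior count of 2; list p-values were adjusted over the lists of a comparison. Shares of counts were compared with exact two-sided permutation tests of 3 against 3 libraries, whose smallest p is 0.1, so that none of them could pass 0.05.

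Allelic balance per gene was tested with the same edgeR test on genome 1 and genome 2 counts as 2 columns per library, a block per library and an allele by group term, over genes with at least 20 allele-resolved reads in every library compared. The genome 2 share is genome 2 reads as a percent of genome 1 plus genome 2 reads. The pooled X-linked share left out Xist. Autosomal genes were measured the same way, but many had reads of nearly 1 genome only, so that their pooled share is no measure of an even hybrid background.

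The tests of the comparisons, the gene lists, the rule for named genes and all alternatives but 1 were chosen before the data were examined. Chosen afterwards were the gene lists without 1 library, the exact tests of X-linked minus autosomal medians, of pooled distal X reads and of the mitochondrial share, and several tests of explanations, each named where it is given. Named genes are Sirt7, Xist and Tsix, the 8 genes with the largest rise and the 8 with the largest fall per comparison (adjusted p at most 0.05, mean log2 CPM of at least 2, groups that do not overlap, no predicted-gene symbol), and up to 4 members of each list with the smallest adjusted p; for allelic balance, Xist, Tsix, the listed X-inactivation centre and escape genes, and the 8 X-linked genes with the largest change each way. The lists were naive pluripotency, formative and primed state, neural, mesoderm, definitive endoderm, primitive endoderm, trophoblast, 2-cell-like state, germline, feeder fibroblast, X-inactivation centre, factors of X inactivation, escape genes, sirtuins, ribosome biogenesis, cytosolic ribosomal proteins, mitochondrial ribosome, nuclear genes of oxidative phosphorylation, mitochondrially encoded genes, p53 targets, integrated stress response, glycolysis, cholesterol synthesis, cell cycle, imprinted genes, Hox genes, interferon response and Y-linked genes; no member of the Y-linked list passed the filter. Some genes stand on several lists, such as Hand1 on mesoderm and trophoblast. Atp5o, Ddit3 and Aldoa, whose symbols matched more than 1 identifier, were left out of the lists.

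The expression test was checked on simulated counts in which 200 known genes above a minimum level were changed. Many more genes changed over 7 days in the data, so the rates over days need not hold there. It recovered 44.0% of 2-fold and 85.0% of 4-fold changes for knockout against wild type at day 0, and 46.5% and 84.8% at day 7. For day 7 against day 0 it recovered 45.5% and 82.8% in wild type and 39.0% and 85.9% in knockout, and for the interaction 28.0% and 68.0%, on 18500 to 18645 genes. The allelic test recovered 45.0% of 4-fold and 75.0% of 16-fold changes of the odds of genome 2 for the genotypes at day 0, 35.0% and 81.0% at day 7, 46.0% and 83.0% over days in wild type and 50.0% and 81.0% in knockout.

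Alternatives were DESeq2 1.42.0, DESeq2 size factors, no filter on low counts, only the 6 libraries compared, a replicate block, leaving out each library in turn, camera with an estimated correlation, fry, other minimum read numbers for the allelic test, and shares over other sets of genes. The allele-resolved transcript table was not used here, and the transcript table of all reads was used only to look at Sirt7. P-values measure the spread between these samples, which may be technical, since the labels do not say that replicates were separate cultures.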

Results

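RNA of female hybrid mouse ES cells was measured in 4 groups of 3 libraries, wild type and libraries labelled knockout of Sirt7, each at day 0 with LIF and at day 7 after its withdrawal. Library totals ran from 25190483 to 69079368 counts, 19235 genes were tested, and 29.7 to 32.0% of the gene reads of a library could be given to genome 1 or genome 2.

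Sirt7 (chromosome 11, 120618372 to 120625240, GRCm38), the gene named as deleted, had more reads in the libraries labelled knockout than in wild type. Its level was 19.2, 23.8 and 16.9 CPM in the knockout libraries of day 0 against 12.7, 8.03 and 10.3 CPM in wild type, and 25.1, 20.1 and 23.8 against 10.2, 10.6 and 15.3 CPM at day 7. The log2 difference was 0.95 (SE 0.21) at day 0 and 0.94 (SE 0.21) at day 7, with the groups apart on both days. By edgeR over all genes this did not pass (adjusted p = 0.182 and 0.299), while over the sirtuin list alone it did (adjusted p = 0.00692 and 0.00719), and DESeq2 called it on both days (0.94 each). Over the fits without 1 library the edgeR adjusted p stayed between 0.137 and 0.713. Between days Sirt7 was 0.22 higher in wild type and 0.21 higher in knockout at day 7, and neither passed. By transcript, the longest protein-coding form had 3.90 ± 2.95 CPM in knockout and 0.217 ± 0.220 in wild type at day 0, but 0.0224 ± 0.0388 and 2.51 ± 1.68 at day 7. A retained-intron form of Sirt7 over the whole gene had 5.22 ± 4.45 and 2.33 ± 1.91 CPM at day 0 and 9.20 ± 4.45 and 3.74 ± 0.963 at day 7. No transcript of Sirt7 was absent from both knockout groups and present in both wild type groups, and these transcript values were not tested. The labels do not give the deleted part of the gene, and an exchange of the genotype labels cannot be excluded from these counts. The groups are called knockout and wild type by their labels alone, and each direction between genotypes below would turn if the labels were exchanged.

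**Figure D1:**
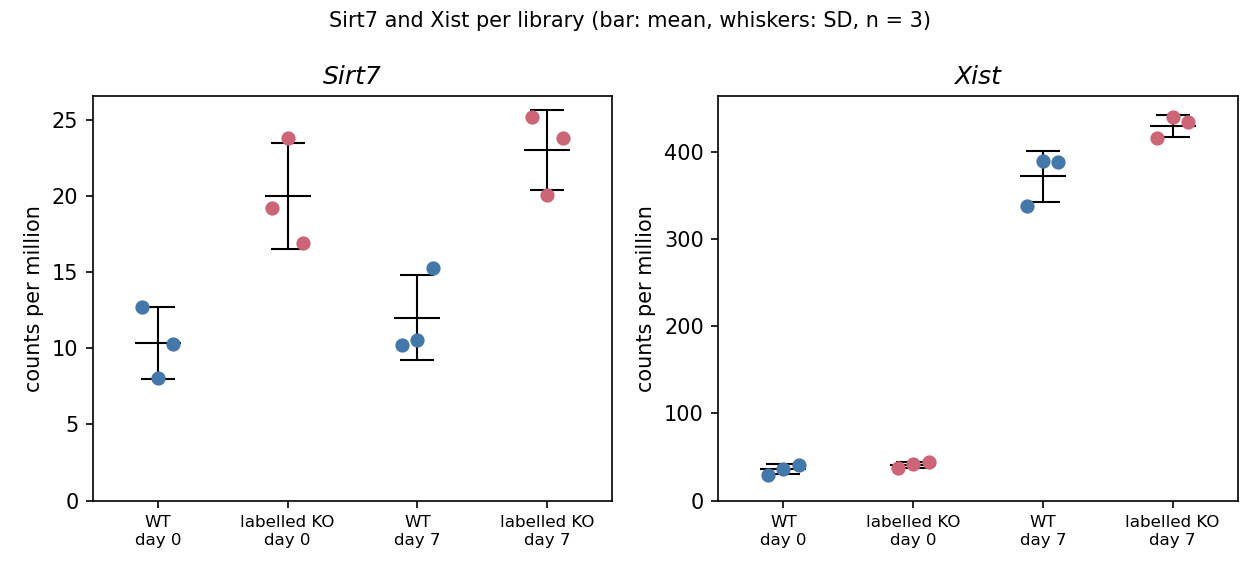
Level of Sirt7 and Xist in CPM per group, with a dot per library, bars at the mean of n = 3 and whiskers of 1 SD. Sirt7 lay at 19.96 and 23 CPM in libraries labelled knockout against 10.3 and 12 CPM in wild type, and Xist was higher at day 7 in both genotypes.

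Knockout against wild type at day 0 asks what differs in undifferentiated cells. Esrrb, a transcription factor of naive pluripotency, was 2.40 log2 units higher in knockout (SE 0.22, adjusted p = 0.00147), with 231 ± 74.5 CPM against 43.8 ± 9.26. The ephrin receptor gene Epha4 was 2.06 higher (SE 0.17, adjusted p = 0.00126, 39.0 ± 9.85 against 9.33 ± 0.788 CPM), the histone deubiquitinase gene Mysm1 1.66 higher (SE 0.15, adjusted p = 0.00147) and the mitochondrial ribosome gene Mrps23 1.35 higher (SE 0.10, adjusted p = 5.47e-04). Slc25a51 (1.74, SE 0.28), Pogz (1.47, SE 0.22), Cdc42bpb (1.3, SE 0.18), Tek (1.29, SE 0.18), the p53 target Zmat3 (0.96, SE 0.13) and Pecam1 (0.46, SE 0.07) were also higher, with adjusted p from 0.0234 to 0.046. Lower in knockout were Emp1 (-1.89, SE 0.28, adjusted p = 0.036), Cybc1 (-1.43, SE 0.18, adjusted p = 0.0207), Rragd (-1.18, SE 0.17, adjusted p = 0.0313), Cc2d1a (-0.67, SE 0.11, adjusted p = 0.046) and the X-linked phosphatase gene Dusp9 (-0.57, SE 0.08, adjusted p = 0.036, 270.5 ± 12.3 against 402 ± 48.7 CPM).

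By edgeR 25 genes differed at day 0, 17 higher and 8 lower in knockout, and 2298 had an unadjusted p under 0.05. DESeq2 called 330, 24 of them shared. A fit to the 6 day 0 libraries alone called 0 (1372 unadjusted), and without the filter on low counts Cc2d1a (adjusted p = 0.104) and Pecam1 (adjusted p = 0.200) were not called. Of the 25 genes, 13, 16 and 11 were still called without knockout replicate 1, 2 or 3 of day 0, and 12, 9 and 13 without wild type replicate 1, 2 or 3. Esrrb, Epha4, Mysm1, Mrps23 and Cybc1 were called in each of these 6 fits, while each of the other 10 named genes was lost in at least 3 of them, with a highest adjusted p between 0.0602 for Zmat3 and 0.127 for Pecam1.

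Among the fixed gene lists at day 0, the 31 Hox genes were lower in knockout, with a median log2 difference of -0.57 (-0.59 with genes at 0 set to their bound). Of these genes 4 had no read in 1 of the groups and 1 was at the floor in both, so that part of the list was nearly silent at day 0. Hoxd9 was 1 of the lower members, at -1.19 (adjusted p = 0.056 over all genes), and passed over the list alone. The 79 cytosolic ribosomal protein genes had a median of -0.14 with only 6 positive, the 54 nuclear genes of oxidative phosphorylation -0.13 with 6 positive, and the 41 genes of the mitochondrial ribosome -0.12 with 5 positive, Mrps23 among these. The 15 mitochondrially encoded genes were all positive, with a median of 0.16, and mt-Nd5 (0.40), mt-Nd4l (0.56), mt-Atp8 (0.49) and mt-Co1 (0.26) passed over the list alone. P53 targets had a median of 0.24 with 20 of 26 positive, 1 member (Zmat3) passing over all genes and 3 (Zmat3, Polk and Sesn2) over the list alone, and glycolysis a median of 0.12.

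These 7 lists passed camera at day 0. Adjusted p for Hox genes was 4.61e-04 but adjusted p = 0.0594 with an estimated correlation. For cytosolic ribosomal proteins it was 1.22e-06, but adjusted p = 0.672 with an estimated correlation. Oxidative phosphorylation gave 3.75e-06, but adjusted p = 0.570 with an estimated correlation, and the mitochondrial ribosome 2.59e-04, but adjusted p = 0.575 with an estimated correlation. Mitochondrially encoded genes gave 3.73e-04, but adjusted p = 0.595 with an estimated correlation. P53 targets gave 3.46e-04, but adjusted p = 0.434 with an estimated correlation, and glycolysis 0.0450, but adjusted p = 0.570 with an estimated correlation.

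Several of these day 0 lists depended on 1 library. Without knockout replicate 1 of day 0 the median of mean log2 CPM differences was -0.0156 for cytosolic ribosomal proteins (-0.148 with all libraries), which no longer passed camera (adjusted p = 0.613), and -0.0656 for the mitochondrial ribosome (-0.122 with all), which did not pass either (adjusted p = 0.114). Oxidative phosphorylation went from -0.136 to -0.0693 without that library and still passed. The mitochondrial ribosome was at -0.205 and -0.195 without knockout replicate 2 or 3. Mitochondrially encoded genes went from 0.168 to 0.0628 without wild type replicate 1 (adjusted p = 0.141) and to 0.108 without knockout replicate 3. The mitochondrial share of counts was 4.12 ± 0.238% in knockout and 3.61 ± 0.402% in wild type (exact p = 0.2), a difference of 0.512 points that was 0.291 without wild type replicate 1. Glycolysis was lost without knockout replicate 1 or 2 and without wild type replicate 1 (0.0838) or 2, with adjusted p up to 0.204. Hox genes and p53 targets passed in each of the 6 fits. Formative and primed genes passed without knockout replicate 3 (adjusted p = 0.0369) or wild type replicate 1 (0.0167), factors of X inactivation without knockout replicate 2 (0.0155) or wild type replicate 1 (0.0483), cholesterol synthesis without knockout replicate 3 (0.0236) or wild type replicate 3 (0.0265) and cell cycle genes without knockout replicate 2 (0.0364).

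The other lists did not pass at day 0. Medians were 0.11 for naive pluripotency (1 member higher, Esrrb), 0.07 for the formative and primed state (Otx2 at 0.76 passed over the list alone), -0.18 for neural genes, -0.19 for mesoderm (Pecam1 higher, and over the list alone also Eomes at 0.45 and Etv2 at -0.68), 0.09 for primitive endoderm, -0.22 for trophoblast, -0.11 for the 2-cell-like state, -0.02 for germline and 0.09 for feeder fibroblast genes. Definitive endoderm (-0.08) and the integrated stress response (-0.06) had a negative median and mean while the camera test pointed up. The X-inactivation centre (0.21, Cdx4 at 1.01 over the list alone), factors of X inactivation (0.16), escape genes (0.14, Car5b at 1.5 and Usp9x at 0.36 over the list alone) and sirtuins (0.06) did not pass either. Ribosome biogenesis (-0.02), cholesterol synthesis (0.17), cell cycle (0.07), imprinted genes (0.02, mean -0.03) and interferon genes (0.08, with a test pointing down) complete the lists.

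Knockout against wild type at day 7 asks what differs after 7 days of differentiation. Mrps23 was again higher in knockout, by 1.20 log2 units (SE 0.10, adjusted p = 0.00183, 36.5 ± 0.169 against 15.9 ± 1.57 CPM). Lower were the histone gene H2aj (-2.55, SE 0.27, adjusted p = 0.00794, 9.89 ± 2.61 against 58.0 ± 7.42 CPM) and the germline gene Morc1 (-3.85, SE 0.42, adjusted p = 0.00794, 0.0388 ± 0.0342 against 0.610 ± 0.127 CPM). Aoah had 0 reads in knockout and 31 in wild type at day 7 and was at least 7.51-fold lower (adjusted p = 0.00794). Ankrd45, which falls outside the rule for named genes and was looked at after its values were seen, was listed at 0 in knockout and at 0.402 ± 0.133 CPM in wild type (adjusted p = 0.00874). Morc1 and Aoah were far higher at day 0, with 172 and 25.5 CPM in knockout and 156 and 22.7 CPM in wild type.

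These 5 genes (1 higher, 4 lower) were all that edgeR called at day 7, with 1573 under an unadjusted p of 0.05 and 133 by DESeq2, 5 of them shared. A fit to the 6 day 7 libraries alone called 9 genes, with only 2 of these 5 among them, and Morc1 was not called (adjusted p = 0.186). All 5 genes remained without any 1 of the 6 day 7 libraries, while the count rose to 13 without knockout replicate 1, to 8 without knockout replicate 3 and to 8 without wild type replicate 2.

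Hox genes were lower in knockout at day 7 as well, with a median of -0.57 and 3 of 31 positive, and Hoxa7 (-1.92), Hoxb6 (-0.62) and Hoxc9 (-1.19) passed over the list alone. Of the 23 genes of the integrated stress response 19 were negative (median -0.19), and 7 passed over the list alone, among them Asns (-0.45, adjusted p = 0.0622 over all genes), Phgdh (-0.49), Shmt2 (-0.42) and Slc7a5 (-0.58). Cytosolic ribosomal proteins had a median of -0.24 with 4 of 79 positive, the mitochondrial ribosome -0.17, oxidative phosphorylation -0.12 and ribosome biogenesis -0.10. Imprinted genes (-0.14) held 3 members that were lower over the list alone, Meg3 (-0.71), Phlda2 (-0.53) and Rtl1 (-0.78). Definitive endoderm (-0.24) and cholesterol synthesis (-0.09, with Mvd at -0.35 over the list alone) were lower, while escape genes (0.17, 15 of 20 positive) and mitochondrially encoded genes (0.13, 14 of 15 positive) were higher. Apart from Mrps23, no gene of these 11 lists passed over all genes by edgeR.

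Of these 11 lists, Hox genes passed camera at the preset correlation (adjusted p = 7.51e-06) and also with an estimated correlation (adjusted p = 0.0122). The integrated stress response gave 1.60e-04, but adjusted p = 0.294 with an estimated correlation. Cytosolic ribosomal proteins gave 2.62e-14, but adjusted p = 0.511 with an estimated correlation. The mitochondrial ribosome gave 0.00104, but adjusted p = 0.538 with an estimated correlation, and oxidative phosphorylation 1.18e-04, but adjusted p = 0.511 with an estimated correlation. Ribosome biogenesis gave 0.00199, but adjusted p = 0.487 with an estimated correlation, and imprinted genes 0.00187, but adjusted p = 0.0672 with an estimated correlation. Definitive endoderm gave 0.0323, but adjusted p = 0.294 with an estimated correlation, and cholesterol synthesis 0.0180, but adjusted p = 0.350 with an estimated correlation. Escape genes gave 0.00199, but adjusted p = 0.168 with an estimated correlation, and mitochondrially encoded genes 0.00199, but adjusted p = 0.599 with an estimated correlation.

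Without 1 of the 6 day 7 libraries, 4 of the 11 lists lost their call in some fits. The mitochondrial ribosome went from -0.164 to -0.0990 without wild type replicate 1 (adjusted p = 0.0653) and mitochondrially encoded genes from 0.129 to 0.0754 without knockout replicate 2 (adjusted p = 0.0862). Definitive endoderm was lost without knockout replicate 2 or wild type replicate 1 (-0.154, adjusted p = 0.104 each), and cholesterol synthesis without knockout replicate 1 (adjusted p = 0.0545) or wild type replicate 2 (adjusted p = 0.122). Without wild type replicate 1 escape genes were at 0.0937 (0.167 with all) and still passed, as did imprinted genes at -0.202 (-0.132 with all) without wild type replicate 3. Naive pluripotency genes passed without knockout replicate 1 (adjusted p = 0.0421).

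The other lists did not pass at day 7. Medians were -0.13 for naive pluripotency (Dppa5a at -0.68 passed over the list alone), 0.03 for the formative and primed state, -0.05 for mesoderm and 0.03 for trophoblast (Hand1, on both, at -0.37 over each list alone), -0.09 for primitive endoderm and -0.02 for cell cycle genes. Neural genes (0.06, mean -0.10) and the 2-cell-like state (-0.24, mean 0.11) had a median and a mean of opposite sign, as had glycolysis (-0.10, mean 0.07, with Slc2a1 at -0.30, Pfkfb3 at 0.98 and Slc2a3 at 1.94 over the list alone). Feeder fibroblast genes had a median of -0.03 (Col1a2 at -0.76 over the list alone), the X-inactivation centre 0.17, factors of X inactivation -0.02, sirtuins 0.06, p53 targets 0.04 and interferon genes -0.08 (Oas2 at 3.28 over the list alone). Trophoblast genes had a mean of -0.20 and factors of X inactivation one of 0.01, each against the sign of its median. The germline median was 0.00, or -0.48 with genes at 0 set to their bound.

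**Figure D2:**
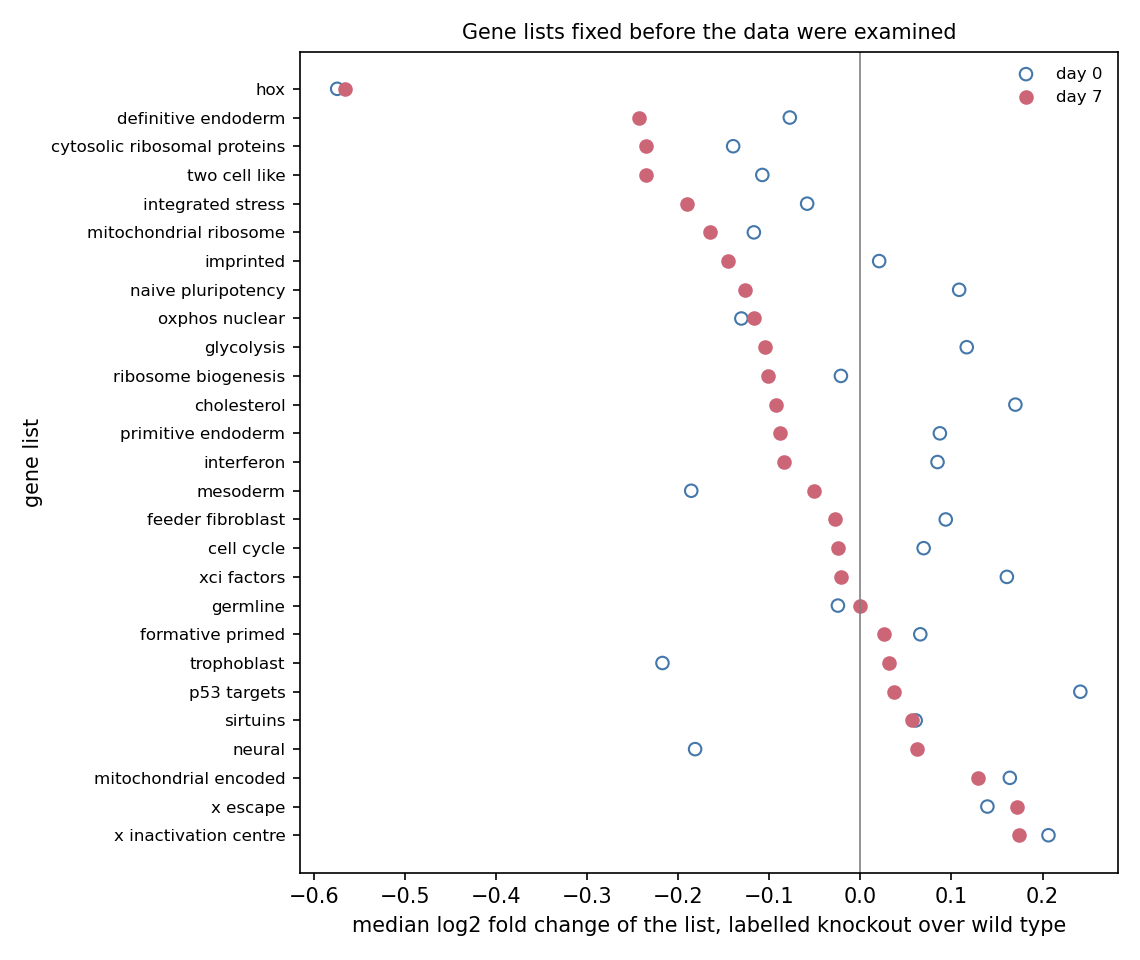
Median log2 fold change of labelled knockout over wild type for each gene list, open at day 0 and filled at day 7 (n = 3 against 3 libraries). Hox genes stood lowest, at -0.57 on both days, and most other medians lay within 0.24 of 0.

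Most genes differed between day 7 after LIF withdrawal and day 0 with LIF in both genotypes. No day 7 group was kept with LIF, so that its loss cannot be told apart from time in culture. Nanog fell by 5.20 log2 units in wild type and by 4.97 in knockout (SE 0.09, adjusted p = 1.74e-11 in wild type), from 1028 ± 36.3 to 28.0 ± 1.34 CPM in wild type, and Klf4 (-4.56 and -4.78), Pou5f1 (-4.18 and -3.90) and Dppa5a (-6.65 and -7.31) fell with it. The mesoderm and trophoblast gene Hand1 rose by 9.63 and 9.04 (SE 0.13 in wild type, adjusted p = 4.91e-12), reaching 1945 ± 119 CPM in wild type. Pdgfra rose by 7.06 and 7.09, T by 8.09 and 8.33, Krt18 by 7.21 and 7.01 and Cdx2 by 8.79 and 9.29. Svep1 had no read in wild type at day 0 and rose at least 3230-fold (2869-fold in knockout), Hoxb6 at least 1953-fold and 1276-fold, and Mymx and Arl14epl, without a read at day 7, were at least 1789-fold and 1214-fold lower in wild type.

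In wild type 6335 genes rose and 6184 fell by edgeR, 12519 in all, and in knockout 5980 and 6216, 12196 in all. DESeq2 called 13321 and 12957, and the fits without 1 library 11284 to 12235.

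Naive pluripotency genes fell in both genotypes (25 of 29 in each, 2 rose, medians -5.15 in wild type and -5.06 in knockout), as did germline genes (18 of 18 in each, medians -6.83 and -7.48, or -6.22 and -6.43 with genes at 0 set to their bound). Of 16 genes of the 2-cell-like state 15 fell in each, Zscan4c by 5.70 and 4.58 (medians -4.18 and -3.8). Mesoderm genes rose (24 of 30 in wild type and 25 in knockout, 3 fell in each, medians 3.92 and 3.8), and feeder fibroblast genes, many of them general mesenchymal genes, also rose (21 of 23 in each, Col1a1 by 8.64 and 7.92, Pdgfrb by 7.47 and 7.92, medians 6.18 and 6.86, or 5.79 and 5.65 with bounds). Hox genes rose (22 of 31 in wild type, 24 in knockout, Hoxb2 by 7.59 and 8.44, medians 3.85 and 3.8), as did imprinted genes (22 and 20 of 30, Mest by 5.18 and 5.22, Peg10 by 3.52 and 3.67, medians 2.28 and 1.66) and genes of cholesterol synthesis (23 and 22 of 24, Cyp51 by 2.91 and 2.74, medians 2.27 and 1.92). By camera, adjusted p for these 8 lists ran from 9.43e-12 for naive pluripotency to 1.75e-04 for the 2-cell-like state in wild type, and all 8 passed with an estimated correlation in both genotypes, the 2-cell-like state at 0.0471 and 0.0398.

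Definitive endoderm genes rose in part (13 of 18 in each genotype, median 4.26 and 4.13, or 3.79 in knockout with bounds), and so did those of primitive endoderm (13 and 12 of 23, Gata4 by 4.70 and 4.47, medians 1.47 and 0.92). Cytosolic ribosomal protein genes fell (77 and 75 of 79, X-linked Rps4x by 1.57 and 1.64, medians -0.87 and -0.98), as did ribosome biogenesis genes (39 and 38 of 45, Dkc1 by 1.91 and 2.05, medians -0.68 and -0.72), genes of the mitochondrial ribosome (29 and 30 of 41, Mrpl24 by 1.89 and 1.74, medians -0.65 and -0.64) and of oxidative phosphorylation (46 and 51 of 54, Cox7b by 1.67 and 1.72, medians -0.66 and -0.63). Definitive endoderm had a camera adjusted p of 0.00304 in wild type and 0.00593 in knockout, but adjusted p = 0.0575 and 0.0761 with an estimated correlation. Primitive endoderm had 0.0199 and 0.0355, but adjusted p = 0.0934 and 0.128 with an estimated correlation, and in knockout it was lost without replicate 3 of day 7 (adjusted p = 0.0532) and had a median of 0.777 without replicate 3 of day 0 (1.49 with all, on mean log2 CPM). Cytosolic ribosomal proteins had 3.49e-13 and 6.43e-14, but adjusted p = 0.370 and 0.326 with an estimated correlation. Ribosome biogenesis had 4.16e-07 and 8.77e-08, but adjusted p = 0.0934 and 0.0816 with an estimated correlation. The mitochondrial ribosome had 2.27e-05 and 2.87e-05, but adjusted p = 0.351 and 0.326 with an estimated correlation. Oxidative phosphorylation had 2.14e-08 and 4.99e-08, but adjusted p = 0.232 and 0.251 with an estimated correlation.

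Lists that did not pass as a whole over 7 days still held many changed genes, given here as counts in wild type and then in knockout. Formative and primed genes rose in 10 and 9 and fell in 7 and 7 of 19 (Fgf5 rose by 6.18, Foxd3 fell by 6.68). Neural genes rose in 7 and 8 and fell in 8 and 8 of 20 (Tubb3 fell by 2.38, Stmn2 by 3.03). Trophoblast genes rose in 6 and 7 and fell in 4 and 4 of 12. Factors of X inactivation rose in 17 and 13 and fell in 3 and 3 of 30 (Pcgf5 rose by 3.75, Eed fell by 1.31). Escape genes rose in 9 and 8 and fell in 7 and 7 of 20 (Bgn rose by 4.01, Utp14a fell by 2.09), and the X-inactivation centre rose in 5 and 5 and fell in 3 and 4 of 10. P53 targets rose in 13 and 10 and fell in 7 and 8 of 26 (Plk2 rose by 3.35, Plk3 fell by 2.29). Genes of the integrated stress response rose in 6 and 5 and fell in 13 and 14 of 23 (Asns fell by 1.83), and those of glycolysis rose in 5 and 6 and fell in 6 and 10 of 20 (Slc2a1 rose by 3.30, Pdk1 fell by 1.70). Cell cycle genes rose in 9 and 7 and fell in 14 and 18 of 34 (Ccne1 fell by 2.74). Interferon genes rose in 8 and 6 and fell in 10 and 11 of 21 (Oas1a fell by 5.35). Mitochondrially encoded genes rose in 2 and 1 and fell in 7 and 9 of 15 (a list that passed in wild type without wild type replicate 1 of day 0, adjusted p = 0.0350), and sirtuins rose in 1 and 1 and fell in 2 and 2 of 7 (Sirt2 rose by 1.64, Sirt6 fell by 1.26). The log2 changes in brackets are those of wild type. Median and mean had opposite signs in wild type for neural (-0.18 and 0.18), interferon (-0.50 and 0.53) and glycolysis genes (-0.08 and 0.14), and did so for the same 3 lists and for escape genes (-0.02 and 0.67) in knockout. In wild type both were positive for escape genes (0.17 and 0.70) while the test pointed down.

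The interaction asks whether the change over 7 days differs between the genotypes. It passed for 5 genes, each with a lower change in knockout. Esrrb fell further in knockout by a difference of -2.92 (SE 0.32), since it started higher, and the difference was -2.05 for Epha4 (SE 0.24), which rose less, and -3.99 for Morc1 (SE 0.46), with an adjusted p of 0.0152 for each. Aoah (fitted -6.20) and Ankrd45 (fitted -6.65) had no read in knockout at day 7, so that their fitted values depend on the prior count, with adjusted p = 0.0152 and 0.0301. By edgeR 1319 genes had an unadjusted p under 0.05, and DESeq2 called 129, 5 of them shared.

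Without knockout replicate 3 of day 7 the interaction passed for 0 genes by edgeR, with an adjusted p of 0.0580 for Aoah, Morc1, Esrrb and Epha4, and the call for Morc1, genotype by day interaction, was also lost without knockout replicate 1 of day 7 (adjusted p = 0.0511). The count was 15 without knockout replicate 1 or 2 of day 0, 14 without knockout replicate 3 of day 0, and 12 without wild type replicate 2 of day 0. It was 9 without wild type replicate 1 of day 0 or of day 7, and 8 without wild type replicate 3 of day 0 or knockout replicate 1 of day 7. Without the filter on low counts it was 8. Among lists, the integrated stress response (median difference -0.30) and cholesterol synthesis (-0.24) passed camera, with adjusted p of 0.00583 and 0.00172, but adjusted p = 0.453 each with an estimated correlation. The integrated stress response was lost without knockout replicate 2, wild type replicate 2 or wild type replicate 3 of day 0 (adjusted p = 0.0691, 0.0572 and 0.0638) and was at -0.199 without knockout replicate 3 of day 7. Naive pluripotency genes passed without knockout replicate 1 of day 7 (adjusted p = 0.0392), cytosolic ribosomal proteins without knockout replicate 1 of day 0 (2.42e-09), p53 targets without knockout replicate 3 of day 0 (0.0275) or wild type replicate 1 of day 7 (0.0307), and glycolysis without wild type replicate 2 of day 7 (0.0460). For Hox genes the median difference was -0.05 and did not pass (adjusted p = 0.940).

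Xist (X chromosome, 103460366 to 103483254, GRCm38), the RNA that coats the inactive X, rose by 3.38 log2 units over 7 days in both genotypes (SE 0.12, adjusted p = 1.48e-09 in wild type and 1.56e-09 in knockout). It went from 35.6 ± 5.73 to 372 ± 29.4 CPM in wild type and from 41.3 ± 3.45 to 430.5 ± 12.6 CPM in knockout. Between the genotypes Xist was 0.21 higher in knockout on both days (SE 0.11), which did not pass (adjusted p = 0.479 and 0.671). Its antisense partner Tsix (103431517 to 103484957) fell by 5.84 in wild type (SE 0.99, adjusted p = 3.30e-04) and by 5.93 in knockout (SE 1.01, adjusted p = 3.48e-04), and its differences between genotypes (-0.08 at day 0 and -0.17 at day 7) did not pass and had no stable sign. For Tsix, knockout against wild type at day 0, the value was 0.46 without knockout replicate 2 and 0.63 without wild type replicate 2, and for Tsix, knockout against wild type at day 7, it was 0.27 without wild type replicate 1.

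X-linked genes as a set asked for the dosage of the X chromosome in knockout. Over 768 X-linked and 18413 autosomal genes the difference in median log2 change between knockout and wild type was 0.05 at day 0 and 0.05 at day 7. It ran from 0.0182 without knockout replicate 1 of day 0 to 0.0745 without knockout replicate 2 of day 0. At day 7 it ran from 0.0229 without wild type replicate 1 of day 7 to 0.0499 without wild type replicate 3 of day 7. Camera gave p = 0.194 and 0.0761, and 3 and 2 of the 10 permutations of the libraries gave a p as small. Over 7 days the X-linked genes fell relative to autosomal genes, by a difference of -0.46 in wild type and -0.47 in knockout, and in wild type 194 of them rose and 331 fell. Camera gave p = 0.00603 and 0.00760, and 1 of 10 permutations, the real one, gave a p as small in each genotype. The other permutations mix the days unevenly and keep part of this change, so that they are no measure of chance. The difference of these changes between genotypes was 0.00 (camera p = 0.794, reached in 53 of 60 permutations). Without wild type replicate 3 the day 7 difference between genotypes (0.05) passed camera, and over genes with a mean log2 CPM of at least 2 the day 0 difference (0.07) did, so those 2 results depend on that library and that minimum. Taken per library, the median log2 CPM of X-linked minus that of autosomal genes was higher in all 3 knockout than in all 3 wild type libraries on both days, by 0.09 at day 0 (-0.51 ± 0.03 against -0.60 ± 0.06) and by 0.13 at day 7 (-0.80 ± 0.02 against -0.94 ± 0.05), with exact p = 0.1 on each day, the smallest possible. The share of all counts on X-linked genes was 3.91 ± 0.0298% in wild type and 3.99 ± 0.10% in knockout at day 0 (exact p = 0.4), and 3.01 ± 0.118% and 3.12 ± 0.0107% at day 7 (exact p = 0.1). The day 7 difference of 0.115 points was 0.0470 without wild type replicate 1 of day 7 and 0.152 without wild type replicate 2 of day 7. That of day 0 ran from 0.0459 without knockout replicate 1 of day 0 to 0.137 without knockout replicate 2 of day 0. It was lower at day 7 by permutation with p = 0.1 in each genotype, the smallest that 3 against 3 libraries can give.

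Allele-resolved reads asked which X chromosome was in use. At day 0 the genome 2 share of X-linked reads was 53.7 ± 0.479% in wild type and 54.0 ± 0.215% in knockout, and at day 7 it was 91.3 ± 0.413% and 91.7 ± 0.0671%. The change over 7 days was 37.6 points in each genotype (exact p = 0.1, the smallest possible), and the genotypes differed by 0.325 points at day 0 and 0.348 at day 7 (exact p = 0.3 on both days). The day 0 difference ran from 0.151 without wild type replicate 1 of day 0 to 0.598 without wild type replicate 2 of day 0. That of day 7 ran from 0.132 without wild type replicate 3 of day 7 to 0.544 without wild type replicate 1 of day 7. Autosomal reads were 29.1% genome 2 in wild type and 29.0% in knockout at day 0 and 28.0% and 28.1% at day 7. As a median over genes, the autosomal allelic share, day 7 against day 0 in wild type, was 1.45 points higher rather than lower at day 7, and the X allelic share, knockout against wild type at day 0, differed by -0.478 points. Xist went the other way from other X-linked genes, from 47.0 ± 10.3% genome 2 in wild type and 53.8 ± 8.29% in knockout to 0.833 ± 0.135% and 0.401 ± 0.162%, so that at day 7 its reads came almost all from genome 1.

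**Figure D3:**
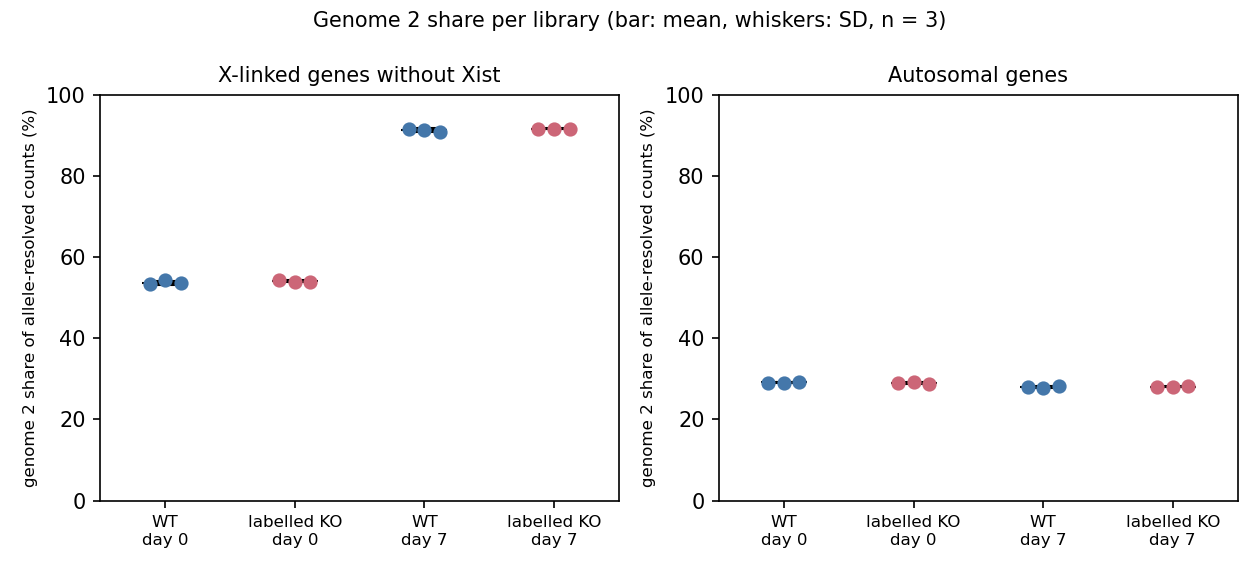
Genome 2 share in percent of allele-resolved reads for X-linked genes without Xist and for autosomal genes, with a dot per library in the 4 groups (n = 3). The X-linked share went from 53.7% to 91.3% in wild type and from 54.0% to 91.7% in knockout, while the autosomal share stayed between 28.0 and 29.1%.

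Per gene, 200 X-linked genes changed their allelic balance over 7 days in wild type, 199 toward genome 2 and only Xist toward genome 1 (adjusted p = 1.30e-05), and 196 in knockout, 195 toward genome 2. Prdx4 went from 32.0 ± 3.8 to 97.9 ± 0.445% genome 2 (adjusted p = 1.04e-06), Timp1 from 34.1 to 100% (adjusted p = 1.02e-04) and Tmsb4x from 13.6 to 99.2%. Among autosomal genes 153 changed in wild type and 79 in knockout, such as Emb, from 79.8 to 48.0% in wild type (adjusted p = 8.24e-05), which was named after its values were seen. Without any 1 library the autosomal count was between 57 (without wild type replicate 2 of day 7) and 95 in wild type, and between 42 (without knockout replicate 3 of day 0 or replicate 2 of day 7) and 126 (without knockout replicate 1 of day 0) in knockout. The difference between the genotypes in this count was not tested. In all, 353 of 9760 genes passed in wild type (1158 unadjusted) and 275 of 9807 in knockout. The wild type count was 219 without wild type replicate 2 of day 7 and 233 without wild type replicate 3 of day 0.

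Some X-linked genes kept many genome 1 reads at day 7. The genome 2 share in knockout and wild type was 59.9 and 64.6% for Kdm6a, 73.4 ± 1.36 and 76.2 ± 0.82% for Eif2s3x, 78.5 and 81.9% for Pbdc1, 83.5 and 84.1% for Ddx3x and 62.8 and 61.1% for Ftx, genes on the lists of escape or of the X-inactivation centre. Kdm5c was at 83.8 ± 1.76 and 69.99 ± 11.2%, while Rlim, Chic1 and Usp9x stood at 92.5% or above in both. Of 286 X-linked genes covered in all libraries, 44 in knockout and 51 in wild type had more than 10% genome 1 reads in all 3 day 7 libraries, 40 of them in all 6. Of these 40 genes 20 were pseudogenes, such as Rpl3-ps1, Gm14586 and Gm8666 at 90.8, 99.2 and 97.8% genome 1 at day 7, whose reads are hard to place, and 8 stood on the lists of escape or the X-inactivation centre.

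Between genotypes, allelic balance differed at day 7 for 3 X-linked genes near the distal end and 1 autosomal gene. Ctps2 (from 162901238) had 100% genome 2 reads in knockout and 94.1 ± 1.98% in wild type (adjusted p = 0.0205), Maged2 (from 150806370) 99.5 ± 0.119 and 96.1 ± 1.12% (adjusted p = 0.0205), and Spin2c (from 153832225) 99.6 ± 0.203 and 96.2 ± 0.463% (adjusted p = 0.0494). Aar2 on chromosome 2, outside the rule for named genes, had 63.5 ± 14.5 and 4.58 ± 2.77% (adjusted p = 0.0429). These were 4 of 11032 genes by edgeR (238 unadjusted). The count was 1, 0 and 3 without knockout replicate 1, 2 or 3 of day 7 and 0 without each of the wild type replicates 1, 2 and 3, and 10 of 354 when X-linked genes alone were tested. At day 0 edgeR called 0 of 10502 genes (294 unadjusted), with 4 without wild type replicate 2 of day 0 and 1 without knockout replicate 1 or 2 of day 0.

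Along the X chromosome the genotypes differed in its distal part, at day 7 by gene and by pooled reads and at day 0 by pooled reads. From 150 Mb on, the median genome 1 share over genes at day 7 was 5.32 ± 0.0839% in wild type and 0.555 ± 0.172% in knockout, and before it 1.47 ± 0.219% and 1.28 ± 0.414%. Over 60 distal genes the median difference was 3.35 points (bootstrap interval over genes 2.41 to 4.03), with 52 higher in wild type, and over 293 proximal genes 0.00 (interval 0 to 0.0272). All 3 wild type libraries lay above all 3 knockout libraries in 33.3% of distal and 3.07% of proximal genes, where chance gives 5% in this direction and 10% in both together. This region was chosen after the values were seen. Without it the X allelic share, knockout against wild type at day 0, differed by -0.0339 points and the X allelic share, knockout against wild type at day 7, by -0.0220 points (exact p = 1 and 0.9). At day 0 the median distal genome 1 share over genes was 48.5 ± 0.974% in wild type and 47.5 ± 0.531% in knockout. Of 56 distal genes with reads in every day 0 library, 30 were higher in wild type, with a median difference of 0.60 points. Pooled over the reads of the region the genome 1 share was 50.4 ± 0.486% and 47.4 ± 0.256% at day 0 and 8.13 ± 0.582% and 5.46 ± 0.251% at day 7. It was lower in knockout by -3.02 and -2.67 points (exact p = 0.1 on both days, the smallest possible). Kdm5c, itself in this region, gave part of the day 0 difference, which without it was -1.73 points (exact p = 0.1), and -1.15 without knockout replicate 1 of day 0 as well. The median log2 expression difference of 109 distal genes at day 7 was 0.00.

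**Figure D4:**
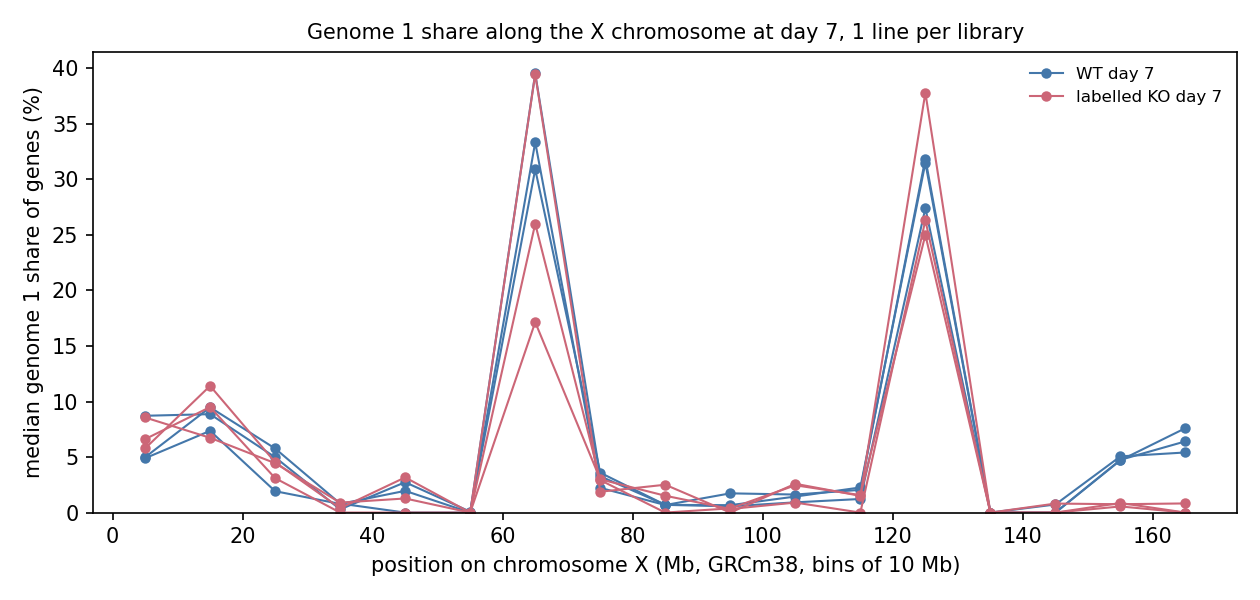
Median genome 1 share in percent over genes per 10 Mb of the X chromosome at day 7, with a line for each of the 6 libraries. From 150 to 160 Mb wild type libraries lay at 4.71 to 5.06% and knockout libraries at 0.553 to 0.862%.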

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

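None of the genes and lists of this part was picked after the result was seen, except Ankrd45, which falls outside the rule for named genes. A difference between the genotypes in the change over 7 days, tested by the interaction term, singled out 5 genes and 2 gene lists. Esrrb (-2.92), which holds ES cells in the naive state, and the ephrin receptor gene Epha4 (-2.05) differed because they were higher in knockout at day 0 and did not pass between genotypes at day 7. Morc1 (-3.99), Aoah (fitted -6.20) and Ankrd45 (fitted -6.65) were alike at day 0 and lower in knockout at day 7, where Aoah and Ankrd45 had no read in knockout, so that both fitted values depend on the prior count. Genes of the integrated stress response (median -0.30) and of cholesterol synthesis (median -0.24) had lower changes in knockout by the preset test, which neither list passed with an estimated correlation. The integrated stress response also lost its call without knockout replicate 2, wild type replicate 2 or wild type replicate 3 of day 0 (adjusted p = 0.0691, 0.0572 and 0.0638).

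Chance could not be excluded for the 5 genes. Of the 60 splits of the 12 libraries that were run, 11 gave as many, the highest other split giving 13. The same holds for the 2 lists, which 39 of 60 splits matched (highest other 9). The split with 13 genes and those with 9 lists kept the 3 wild type libraries of day 7 together. They thus hold the day 7 difference between the genotypes and are no clean measure of chance. Without knockout replicate 3 of day 7 the interaction was past the threshold for 0 genes.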

How the results depend on the processing

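Most results kept their direction and side of the threshold, 738 of 837 values of named genes, 289 of 405 of gene lists, 92 of 100 shares, 56 of 61 of the X-linked set and 64 of 99 counts of genes, and the cause of the differences was not tested. These totals pool all comparisons and count genes never called as kept. Named genes of the change over 7 days lost no call without 1 library. Most genes named as called between genotypes at day 0 lost theirs in some of those fits, Pecam1 in all 6. Of the named genes 84 no longer passed, 4 newly passed and 11 changed sign, and of the lists 62, 45 and 9. DESeq2 called 330 genes between genotypes at day 0, 133 at day 7 and 129 in the interaction, and passed Sirt7 on both days (0.94 and 0.94). The 6 libraries compared alone gave 0 and 9 genes, those of day 7 with 2 of the 5 genes of the main fit, and no filter gave 8 in the interaction. Without 1 library the counts ran from 20 (without knockout day 0 replicate 3) to 55 (without knockout day 0 replicate 2) at day 0, from 6 to 13 (without knockout day 7 replicate 1) at day 7, and from 0 (without knockout day 7 replicate 3) to 15 (without knockout day 0 replicate 1 or 2) in the interaction. Sign changed for Xist, genotype by day interaction, near 0, which was 0.0130 with RLE factors, 0.00666 with DESeq2 and -0.12 to 0.11 without 1 library. Tsix ran from -1.07 to 0.63 at day 0 (without wild type day 0 replicate 2) and from -0.39 to 0.27 at day 7 (without wild type day 7 replicate 1). The X-linked set passed at day 0 over genes with a mean log2 CPM of at least 2 (0.0679), and at day 7 without wild type day 7 replicate 3 (0.0499, the highest of a range from 0.0229). Its interaction was -0.0111 over genes with that minimum and -0.0239 to 0.0284 without 1 library. Fry pointed the other way for trophoblast (median -0.22) and interferon genes (0.0848) at day 0, neural genes at day 7 (0.0621), glycolysis over 7 days in wild type (-0.0833) and the sirtuin interaction (0.0203).

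The X allelic share, knockout against wild type at day 0, was -0.478 as a median over genes, -0.0618 without escape and X-inactivation centre genes and -0.0339 without genes from 150 Mb on, and the X allelic share, knockout against wild type at day 7, was -0.0220 without the latter. As a median over genes the autosomal allelic share, knockout against wild type at day 0, was 0.398, and the autosomal change was 1.45 over days in wild type and 1.61 in knockout, and at day 7 it ran from -0.0235 (without wild type day 7 replicate 2) to 0.117. Genes with a changed allelic balance between genotypes at day 7 numbered 2 with at least 50 reads, 10 among X-linked genes alone and 0 to 3 without 1 library, and at day 0 0 to 4 (without wild type day 0 replicate 2). Over days they ran from 219 (without wild type day 7 replicate 2) to 263 in wild type and from 210 to 302 in knockout.

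With a replicate block 6 genes passed at day 0, 2 at day 7 and 0 in the interaction, and with a replicate block within genotype 0 in the interaction. Fry with the replicate block also pointed the other way for these interferon, neural, glycolysis and sirtuin results (medians 0.0848, 0.0621, -0.0833 and 0.0203). Whether the replicate numbers pair the samples was not settled. Of 18 cases 3 correlated best with their own number, all between the genotypes on the same day, at correlations of 0.0909, 0.0588 and 0.0370. A call lost under the block can therefore not be read either way.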

Other observations

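Hox genes were lower in knockout in each of the 4 clusters at day 7, where the cluster medians were -0.96 for Hoxa, -0.47 for Hoxb, -0.86 for Hoxc and -0.40 for Hoxd, so that 1 cluster alone does not account for the list. At day 0 they were -0.55, -0.96, 0.03 and -0.59, with Hoxc apart from the others. These day 0 values were taken without bounds and rest in part on few reads. Hoxb5 had 0 reads in knockout and 6 in wild type at day 0, and Hoxb6 had no read in either. Hoxa7 (-1.92) and Hoxc9 (-1.19) stood out at day 7. The imprinted genes Igf2 (-1.07) and Meg3 (-0.71) had lower values in knockout at day 7, neither past the threshold over all genes. Hand1, a gene of extraembryonic and lateral mesoderm, reached 1508 ± 27.4 CPM in knockout and 1945 ± 119 CPM in wild type.

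The allelic reads held further structure. Of 9038 covered autosomal genes 49.0% had under 10% genome 2 reads and 44.7% lay between 10 and 90%. By chromosome the part between 10 and 90% ran from 11.2% of covered genes on chromosome 10 to 88.6% on chromosome 13. Whether each autosomal gene carried both genomes was not tested. The pooled autosomal share of 28 to 29% therefore cannot be read as the balance of an even hybrid background. Over the 298 of 557 genes of chromosome 8 at 10 to 90% the median was 67.9% genome 2, with 183 genes under 10% and 76 above 90% left out of it.

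In the distal X pattern the tests of a chromosome-wide difference and of other splits were chosen only after the result was seen. Genes from 150 Mb on kept a median 3.35 points more genome 1 reads at day 7 in wild type than in knockout. Pooled reads of the region also differed at day 0 (50.4 against 47.4%), in part through Kdm5c. Without that gene, knockout minus wild type was -1.73 points at day 0. By gene the day 0 difference was small, with a median of 0.60 points and 30 of 56 genes higher in wild type. Whether the pattern was there before day 7 is therefore not settled. A difference in silencing of this size over the whole X chromosome is argued against by a median difference of 0.00 over genes before 150 Mb. That cut was placed after the values were seen. Genes from 130 to 140 Mb had a median genome 1 share of 0 in all 6 day 7 libraries, so that smaller proximal differences may go unseen. A minority of wild type cells with the distal genome 1 copy active could give an about equal share in each distal gene. The spread over well covered distal genes was an SD of 2.64 points against 3.02 over proximal genes, a ratio of 0.875 and within the bound set beforehand. The proximal spread is nearly as large as the 3.35 points themselves, so the ratio cannot tell an equal share from an unequal one. Mixed or recombined cells remain a candidate explanation that this test does not decide. The 10 splits of the 6 day 7 libraries are too few for a share under 0.05, with 1 split reaching the real 3.35 and 0.939 in the highest other, and a direct effect of the knockout on this region stays open as untested.

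Both tests of the next pattern were written before their result was seen. Of 95 genes above 20 CPM at day 0 and under 2% of that level at day 7, 90 with reads had a median log2 ratio of knockout to wild type of -0.43 (interval -0.59 to -0.23), with 75.6% lower in knockout, among them Morc1 and Aoah. Fewer undifferentiated cells left in the knockout cultures would lower such genes together, and the value of -0.43 leaves this open, since the interval spans the bound of -0.5. Reads of day 0 libraries carried over into wild type day 7 libraries would leave few genes below 0.1% of their day 0 level, and the 7.37% found lies between the bounds of 5 and 20% and decides nothing. A difference in silencing between genotypes, which the design names, stays open as well.

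In the third pattern the length test for oxidative phosphorylation and the tests of 1 library, but for ribosomal proteins at day 7, were chosen only after the result was seen. Ribosomal protein and oxidative phosphorylation genes had day 7 medians of -0.24 and -0.12 in knockout against wild type, but adjusted p = 0.511 each with an estimated correlation, and no member passed over all genes. After a trend of the fold changes with exon length was subtracted, the ribosomal protein median was -0.15 (interval -0.175 to -0.130), so that length is argued against only as the whole cause there. The median of oxidative phosphorylation was then -0.0603 (interval -0.10 to -0.02), which met the bound set for length as a cause. Its interval still lay below 0, so that length may account for part of it. A single library is argued against only for ribosomal proteins at day 7, where the median was -0.17 or lower without any 1 library, since without wild type replicate 1 of day 7 that of oxidative phosphorylation was -0.0813, and without knockout replicate 1 of day 0 the day 0 medians were -0.0156 and -0.0693. A difference of the genotypes in these genes stays open, as do differences in library quality, since the mitochondrial share of counts was 3.38 ± 0.197% in knockout and 3.01 ± 0.238% in wild type at day 7 (exact p = 0.2), 14 of 15 mitochondrially encoded genes were positive, and RNA integrity was not measured.

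No test of this part was chosen after the result was seen, and it counts how many splits of the libraries gave a result as large as the real one. The 10 splits of 6 libraries are too few for a share under 0.05. Every other split of 6 libraries mixes the groups unevenly and so keeps part of any difference between them. Some of the 60 splits of the interaction likewise kept the genotypes apart on 1 day. Over 7 days most genes changed, so the list counts and X-linked p-values of the other splits over days are no measure of chance. For genes called, 1 split reached the 25 at day 0 (highest other 13), 3 reached the 5 at day 7 (highest other 9), 1 the 12519 in wild type (highest other 1) and 1 the 12196 in knockout (highest other 0). For the p of the X-linked set, 3 reached the 0.194 at day 0 (smallest other 0.0962), 2 the 0.0761 at day 7 (0.0733), 1 the 0.00603 in wild type (0.00953) and 1 the 0.00760 in knockout (0.0108). In its interaction 53 of 60 reached 0.794 (0.0270), so that chance is not excluded. For gene lists, 1 reached the 7 at day 0 (highest other 6), 1 the 11 at day 7 (4), 3 the 14 in wild type (15) and 3 the 14 in knockout (14). For allelic balance, all 10 splits reach a count of 0 whatever the data, so that day 0 was not tested in this way (highest other 3), and 1 reached the 4 at day 7 (1), 1 the 353 in wild type (1) and 1 the 275 in knockout (0).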
